A study of Mus musculus with 6 samples.

How the data were processed

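Gene expression was measured in mesenteric lymph nodes of adult mice of 2 genotypes on 6 two-colour Agilent oligonucleotide arrays. Per the labels, 3 arrays held B-TNF KO samples, called B_TNF_KO here, and 3 held TB-TNF KO double samples, called TB_TNF_KO. Per the labels, each sample was RNA from the pooled nodes of 3 mice, labelled with Cy3, and every array carried a common pool of mouse cell line RNA labelled with Cy5. No wild-type sample was analysed here, so the values compare the 2 knockouts with each other.

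Per the file headers, the authors read the scans with Agilent Feature Extraction A.7.5.1 using local background subtraction. The deposited scanner files give spot intensity and local background intensity for both channels, and a log10 ratio of reference over sample. The deposited series table holds log10 values, which followed the processed Cy3 signal of the same array (r across probes, which are not independent replicates, between 0.993 and 0.996) with column medians of 2.98 to 2.99. Its group differences followed the deposited log ratio and not the sample channel alone. The median difference of the ribosomal protein list was 0.4603 with both, against 0.0028 with the sample channel alone. The reference channel thus appears to enter these values, which r across probes does not show. The background step behind them, and any scaling between arrays, stay unknown.

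The mean intensities were background corrected with normexp at an offset of 50 and normalised by loess within each array in limma 3.58.1 (R 4.3.3). Control spots had weight 0 in loess and were then left out, as were 228 outlier spots. Log ratios are log2 of sample over reference. A probe was kept when its sample channel was well above background on at least 3 arrays, which left 40792 of 41006 probes. Spots of a probe were averaged, and a gene with several probes was represented by the one with the highest mean sample signal. Of 41034 spots, 15303 were given a symbol through their accession in a RefSeq table of GRCm38.p6 and 25731 kept the name in the file. The test covered 37048 genes, 12257 of them with a symbol. No genome sequence was used and no position is printed. The RefSeq table gave names and, in the closing section, the order of genes beside Tnf. The sample channel was well above background in 95.91% to 99.61% of spots per array, and the number of arrays limits the precision.

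The groups were compared with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). The design fixed before the data were examined counted all 6 arrays as samples. After the values were seen, the TB_TNF_KO arrays 1 and 2 were found to differ by about the technical noise, as given with the results, so their mean entered as 1 sample and n was 3 against 2. Counts with the 6 arrays counted separately are printed beside it. If arrays 1 and 2 held 1 RNA, that fit counts 1 sample as 2, and its p-values are then too small. Gene lists, 33 fixed before the data were examined, were tested with camera at a preset correlation of 0.01. Where nothing else is said, differences are TB_TNF_KO minus B_TNF_KO with the model's SE. The label of a pool is the only evidence that pools came from separate animals.

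The named genes were set by a rule fixed before the data were examined. It took per direction the 12 genes with a symbol with the largest difference past the threshold. The arrays of one group all had to lie above or below those of the other. Clone names were left out, as were Xist and the Y-linked genes of the sex-linked list, but not other X-linked genes. Open places were filled by the smallest unadjusted p. Tnf, Lta, Ltb, Tnfrsf1a and Tnfrsf1b were also named, with up to 4 members of each list described. No probe was named Tnfrsf1b here, and 1 gene that the rule took is not reported here.

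Each extraction day in the file headers held 1 group, so batch and group cannot be told apart, and no fit with the day as a block could be made. The alternatives covered background correction, normalisation, the sample channel alone, the authors' values, probe filters, the handling of probes, the spread model and array weights. They also covered male pools by the labels, the replicate number as a block and each replicate left out. Data were simulated for this comparison, with 36912 genes and 3 against 2 samples. The fit found 97 of 100 genes changed by 1 and 64 of 100 changed by 0.5 on the log2 scale, with 5 false calls. The simulated errors were independent between genes and samples, with no effect of the day and no shared structure of the samples. With no change simulated, 1808 genes had an unadjusted p under 0.05 in limma, against 1870 higher and 4198 lower in the real data. These rates may therefore not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.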

Results

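The comparison asked which transcripts differed between naive mesenteric lymph nodes lacking TNF in B cells and nodes lacking it in both T and B cells, as the series title frames it. TNF is a cytokine made by many immune cells. Each of the 6 arrays measured 1 pool of 3 mice against the same reference RNA, with 3 arrays per group. Median background-subtracted sample intensity per array was 159 to 203 in B_TNF_KO and 144 to 166 in TB_TNF_KO. For the reference channel it was 280 to 283 in B_TNF_KO and 315 to 362 in TB_TNF_KO, so the groups did not overlap there.

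Tnf, the targeted gene, had a log2 ratio of 0.35 ± 0.15 (SD, n = 3) in B_TNF_KO and -0.74 ± 0.13 (SD, n = 2) in TB_TNF_KO. The difference was -1.09 (SE 0.10), and every TB_TNF_KO array lay below every B_TNF_KO array. Its adjusted p was 0.053 over all genes and 0.00075 adjusted over the list alone, the TNF family list. With the 6 arrays counted separately the adjusted p was 0.0077. A second, dimmer Tnf probe differed by -0.26. The difference was -0.58 without background subtraction and -0.68 with the mean of all probes. Whether either probe lies in the deleted part is unknown, so this does not check the labels. Of its neighbours in function, the lymphotoxin genes Lta and Ltb differed by -0.26 (SE 0.14) and -0.03 (SE 0.07), and the receptor gene Tnfrsf1a by -0.17 (SE 0.07). None of these 3 passed the threshold. Over all alternatives Lta lay between -0.48 and -0.03 and passed in 2 of 27, and its second probe gave -0.04. Tnfrsf1a lay between -0.28 and -0.09.

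Cxcl13, encoding the chemokine that draws B cells into follicles, fell 2.95-fold in TB_TNF_KO. Its log2 ratio was 5.02 ± 0.14 (SD, n = 3) in B_TNF_KO and 3.46 ± 0.08 (SD, n = 2) in TB_TNF_KO, a difference of -1.56 (SE 0.09, adjusted p = 0.026). A second Cxcl13 probe differed by -1.65. For the tested Cxcl13 probe the reference channel differed by -0.75 and the sample channel alone by -1.94. Lyve1, a hyaluronan receptor of lymphatic endothelium, was called lower by -1.22 (SE 0.05, adjusted p = 0.0081). Its second probe differed by -0.03. For the tested Lyve1 probe the reference channel differed by 0.54 and the sample channel alone by -0.42. Prg4, encoding the secreted proteoglycan lubricin, fell by 0.71 on the log2 scale (SE 0.04, adjusted p = 0.029), and its second probe differed by -0.53. The tested Prg4 probe differed by -0.39 in the sample channel alone and by 0.26 in the reference channel. These were 3 of the 5 genes past the threshold. The others, chosen for mention after their values were seen, carry only the clone accessions AK031739 (-1.02, in the sample channel alone -0.63) and AK017936 (-0.98). Cxcl13 and Prg4 no longer passed without B_TNF_KO replicate 1, 2 or 3 or TB_TNF_KO replicate 2 or 3, each left out in turn (adjusted p 0.052 to 0.18). Lyve1 no longer passed without B_TNF_KO replicate 2 or 3 or TB_TNF_KO replicate 3 (adjusted p 0.056 to 0.089).

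**Figure D1:**
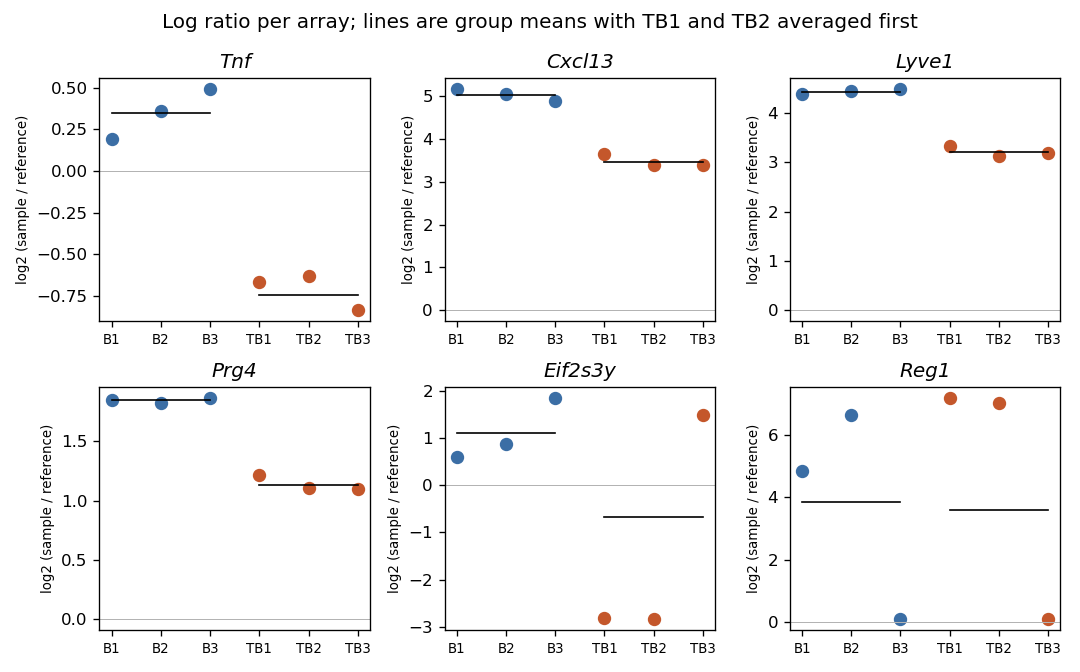
Log2 ratio of sample over reference (y axis) on each array (x axis) for 6 genes, with B_TNF_KO arrays in blue, TB_TNF_KO arrays in orange and lines at group means with TB_TNF_KO arrays 1 and 2 averaged first. Tnf, Cxcl13, Lyve1 and Prg4 separated the groups, while Eif2s3y and Reg1 split the arrays within groups; axes do not all start at 0.

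In all, limma called 0 genes higher and 5 lower among 37048. At an unadjusted p under 0.05 there were 1870 higher and 4198 lower, where chance gives 1852 in total. These were 2596 and 3327 after the GC correction, and 4045 and 4356 with the sample channel alone. With the 6 arrays counted separately the counts were 541 higher and 1734 lower, and with the sample channel alone 257 and 313. The count of lower genes was 0 without B_TNF_KO replicate 2, 0 without B_TNF_KO replicate 3 and 0 without TB_TNF_KO replicate 3. It was 1 without B_TNF_KO replicate 1 and 2 without TB_TNF_KO replicate 2. The groups lay on separate extraction days, so batch and group cannot be told apart. In the reference channel, the same RNA on every array, 3328 genes had higher and 5198 lower values at an unadjusted p under 0.05, and 0 passed the adjusted threshold.

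The other named genes with lower values did not pass, with adjusted p = 0.053 for each, Tnf among them. They included Timp3, an inhibitor of matrix metalloproteinases, at -0.62 (SE 0.05), whose second probe gave 0.09. The cytokine gene Il18 differed by -0.49 (SE 0.04), Nr2f2, a nuclear receptor of venous and lymphatic endothelium, by -0.55 (SE 0.05), and Rpia, an enzyme of the pentose phosphate pathway, by -0.57 (SE 0.05). Arl6, Xlr and Tm6sf1 lay between -0.53 and -0.43, and the second Xlr probe gave -0.19. Over all alternatives Arl6 lay between -0.67 and -0.20 and Xlr between -0.67 and -0.09. Nr2f2 ranged from -0.64 to -0.28 and Timp3 from -0.78 to -0.26.

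None of the 12 named genes with higher values passed, with adjusted p = 0.053 for each. All 12 passed with the 6 arrays counted separately, which takes TB_TNF_KO arrays 1 and 2 as 2 samples. The transcriptional repressor Zbtb7a differed by 1.34 (SE 0.15), the splicing-associated gene Luc7l by 0.76 (SE 0.10) and Ciita, the transactivator of MHC class II genes, by 0.74 (SE 0.07). The second Ciita probe gave -0.07, and the second probes of Luc7l, Creb1 and Cyp4a14 gave 0.27, -0.15 and -0.03. Topors, Cyp4a14, Ccdc77 and Smarca5, a chromatin-remodelling ATPase, lay between 0.55 and 0.62. Spinkl, Rev3l, Supt16, Cacng6 and Creb1 lay between 0.39 and 0.47. Sizes depended on the processing. Over all alternatives Supt16 lay between 0.15 and 0.61, Cacng6 between 0.17 and 0.54, and Creb1 between 0.12 and 0.43. Rev3l ranged from 0.21 to 0.54, Ccdc77 from 0.27 to 0.72 and Ciita from 0.34 to 1.04.

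Of 33 gene lists, 11 passed camera at the preset correlation, 10 of them lower in TB_TNF_KO, and 8 passed with the 6 arrays counted separately. With the correlation estimated from the data 0 passed (smallest adjusted p = 0.61), and 0 passed with fry (smallest adjusted p = 0.054). Of 30 alternatives run for each list, single arrays left out among them, the call was lost in 2 for the follicular dendritic cell list, 4 each for the fibroblast and ribosomal lists, and 6 for the dendritic cell list. It was lost in 8 for the TNF family list, 9 for B cells, 11 for blood endothelium and 13 for interferon-stimulated genes. For lymphatic endothelium it was lost in 18, for macrophages in 19 and for the circadian clock in 21. All alternatives but the estimated correlation and fry kept the preset correlation, so these tallies do not test it. They also count loess with Aquantile, which left log ratios as they were. Male pools by the labels was the same fit as TB_TNF_KO replicate 2 left out. The follicular dendritic cell list, markers of the stromal cells of B cell follicles, was lower (adjusted p = 0.0079, or adjusted p = 0.61 with an estimated correlation). Of its 15 measured members 1 fell over all genes and 5 adjusted over the list alone, namely Cxcl13, Tnfsf11 (-0.38), Bst1 (-0.40), Cilp (-0.84) and Coch (-0.53). Tnfsf11, shared with the TNF family list, had a second probe at -0.07, and Coch was named after its value was seen. Coch and Cilp had dim probes (log2 sample signal 6.8 and 7.5). Of the 15 members 12 had lower and 3 higher values. The bright markers C4b, Clu and Mfge8 differed by only -0.12, -0.14 and -0.12, and Lrat by 0.21. These 4 were also named after their values were seen. The follicular dendritic cell median of -0.12 was -0.19 without B_TNF_KO replicate 3, -0.22 with median centring and -0.24 with the arrays without Y-linked signal left out.

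The TNF family list was lower (adjusted p = 0.028, or adjusted p = 0.61 with an estimated correlation). It holds Tnf, the targeted gene, at -1.09, and was not tested without Tnf. Of its 21 measured members 5 were lower adjusted over the list alone, with Tnfrsf18 at -0.28, Tnfrsf13c, the BAFF receptor gene, at -0.53 and Fasl at -0.22 beside Tnf and Tnfsf11. Fasl was likewise named after its value was seen. Without TB_TNF_KO replicate 3 the list no longer passed (adjusted p = 0.05003), nor with the sample channel alone (adjusted p = 0.25). The TNF family median of -0.09 was -0.17 with median centring and -0.06 with the GC correction and the 6 arrays counted separately. The B cell list was lower (adjusted p = 0.028, or adjusted p = 0.75 with an estimated correlation), with 4 of 18 lower adjusted over the list alone. These were Blk (-0.51), Cd79a (-0.42), Fcrl1 (-0.38) and Tnfrsf13c. With the sample channel alone the B cell median turned from -0.10 to 0.0025 (adjusted p = 0.68). It was -0.16 with median centring, -0.16 without B_TNF_KO replicate 1 and -0.20 without TB_TNF_KO replicate 3. With the arrays without Y-linked signal left out it was -0.06. The B cell list no longer passed without B_TNF_KO replicate 2 (adjusted p = 0.12). The dendritic cell list was lower (adjusted p = 0.019, or adjusted p = 0.61 with an estimated correlation), with 4 of 17 lower adjusted over the list alone, among them the chemokine gene Ccl22 (-0.68), Clec10a (-0.61) and Fscn1 (-0.41), and 1 higher. The dendritic cell median of -0.14 was -0.08 without TB_TNF_KO replicate 2 and -0.21 with median centring, and the list did not pass with the sample channel alone (adjusted p = 0.23). Over all genes, 0 members of these 3 lists passed.

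Stromal lists had adjusted p = 0.016 (fibroblast and extracellular matrix), 0.037 (blood endothelium) and 0.039 (lymphatic endothelium), each lower, and each with adjusted p = 0.61 with an estimated correlation. Without B_TNF_KO replicate 2 the 3 lists no longer passed (adjusted p = 0.12, 0.16 and 0.12). Without TB_TNF_KO replicate 2 the blood and lymphatic endothelium lists did not (0.069 and 0.052), nor did the lymphatic list without TB_TNF_KO replicate 3 (0.51, median -0.06 against -0.15). With the 6 arrays counted separately the blood (adjusted p = 0.063) and lymphatic (adjusted p = 0.14) endothelium lists did not pass. Without background subtraction the fibroblast median went from -0.12 to -0.03 (adjusted p = 0.11) and the lymphatic from -0.15 to -0.06 (adjusted p = 0.11), both losing the call, and the blood endothelium median from -0.18 to -0.08. With the sample channel alone the blood endothelium median was -0.05 (adjusted p = 0.76) and the lymphatic -0.07 (adjusted p = 0.68). Leaving out the arrays without Y-linked signal gave a blood endothelium median of -0.11 and a lymphatic median of -0.24. In the fibroblast list 2 of 18 members, Timp3 and Col14a1 (-0.61), were lower and 1, Fbln2 (0.35), higher adjusted over the list alone, and 0 passed over all genes. The endothelial receptor gene Robo4 differed by -0.38. The lymphatic list held Lyve1, whose second probe differed by -0.03, and, at -0.35, Stab1. With the mean of all probes of a gene the lymphatic list did not pass (median -0.13, camera adjusted p = 0.13).

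Macrophage and monocyte (0.048), circadian clock (0.048) and interferon-stimulated genes (0.031) were also lower by the preset-correlation adjusted p, and lost the call with an estimated correlation (adjusted p = 0.61, 0.61 and 0.85). In the interferon-stimulated list 1 of 24 members, Trim30a (-0.52), was lower adjusted over the list alone. Its median of -0.11 was -0.04 without B_TNF_KO replicate 2 (adjusted p = 0.42) and -0.20 without B_TNF_KO replicate 1 (adjusted p = 2.5e-06). That list also no longer passed without B_TNF_KO replicate 3 (0.076), TB_TNF_KO replicate 2 (0.052) or TB_TNF_KO replicate 3 (0.14), nor with the sample channel alone (0.089). The macrophage list no longer passed without B_TNF_KO replicates 1 (0.052) or 2 (0.23) or TB_TNF_KO replicates 2 (0.071) or 3 (0.38, median -0.03 against -0.10), nor with the 6 arrays counted separately (0.14). The macrophage median was -0.21 with median centring and -0.17 with the sample channel alone. The circadian clock list no longer passed without B_TNF_KO replicates 1 (0.072), 2 (0.068) or 3 (0.079) or TB_TNF_KO replicate 2 (0.069), nor with median centring (0.13) or the sample channel alone (0.12). The circadian clock median of -0.09 was -0.04 without background subtraction (0.054) and -0.04 with the mean of all probes (0.32). The list past the threshold in the higher direction was ribosomal proteins (median 0.42, adjusted p = 3.2e-07, or adjusted p = 0.61 with an estimated correlation), where 18 of 23 members were saturated on at least 1 array. With saturated probes left out the ribosomal median was 0.04 (adjusted p = 0.80), and without B_TNF_KO replicate 3 it was 0.26. It was 0.16 with median centring and 0.0028 with the sample channel alone (adjusted p = 0.76).

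The lists of NF-kB target genes, T cells, NK and cytotoxic cells, and homeostatic chemokines and adhesion each had an adjusted p of 0.082. In the NF-kB list 8 of 37 members were lower adjusted over the list alone, among them Cflar (-0.36), Birc2 (-0.39) and Vcam1 (-0.35). In the chemokine list Il7 was at -0.40 and 6 of 18 members were lower adjusted over the list alone. Ccl21b, named after its value was seen and saturated on all 6 arrays, was higher adjusted over the list alone. The other 18 lists had adjusted p between 0.10 and 0.95.

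**Figure D2:**
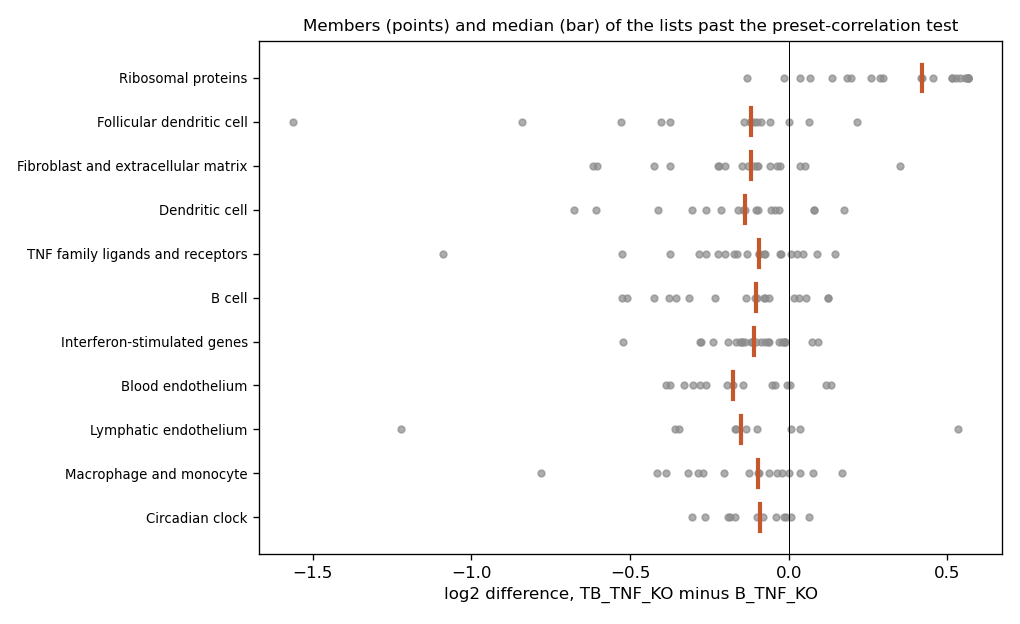
Log2 difference TB_TNF_KO minus B_TNF_KO (x axis) for each measured member (points) of the 11 lists past camera at the preset correlation (y axis), with the median as a bar. Medians of the 10 lower lists lay between -0.18 and -0.09, and ribosomal proteins, mostly saturated, at 0.42.

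Some arrays stood apart within their group. The library labelled TB_TNF_KO replicate 1, male by its label, had a log2 ratio of -2.81 for the Y-linked gene Eif2s3y, and replicate 2, labelled female, had -2.84. The 4 other libraries, all labelled male, lay between 0.59 and 1.83 but were not alike. Eif2s3y was 0.59 and 0.88 on B_TNF_KO arrays 1 and 2, and 1.83 and 1.49 on replicate 3 of B_TNF_KO and TB_TNF_KO. The Y-linked gene Ddx3y was 0.05, 0.53, 1.61 and 1.25 on these arrays in the same order. The cause was not tested. No B_TNF_KO array was as low as TB_TNF_KO arrays 1 and 2, so sex and group cannot be fully told apart. Arrays 1 and 2 of TB_TNF_KO differed in the sample channel by 1.03 times the SD of their reference channels, against 1.21 to 1.93 times for the 14 other pairs, and 4 probes differed over 2-fold, against 25 to 172. The difference was thus about the technical noise of the same RNA on every array, and they were counted as 1 sample. Exocrine pancreas transcripts, markers of a neighbouring organ, were high on B_TNF_KO arrays 1 and 2 and TB_TNF_KO arrays 1 and 2 and near 0 on replicate 3 of both groups. The median of the 18 measured members was 2.94, 4.05 and 0.03 in B_TNF_KO and 4.22, 4.25 and 0.02 in TB_TNF_KO. Reg1, named after its values were seen, reached 7.17 on TB_TNF_KO array 1.

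**Figure D3:**
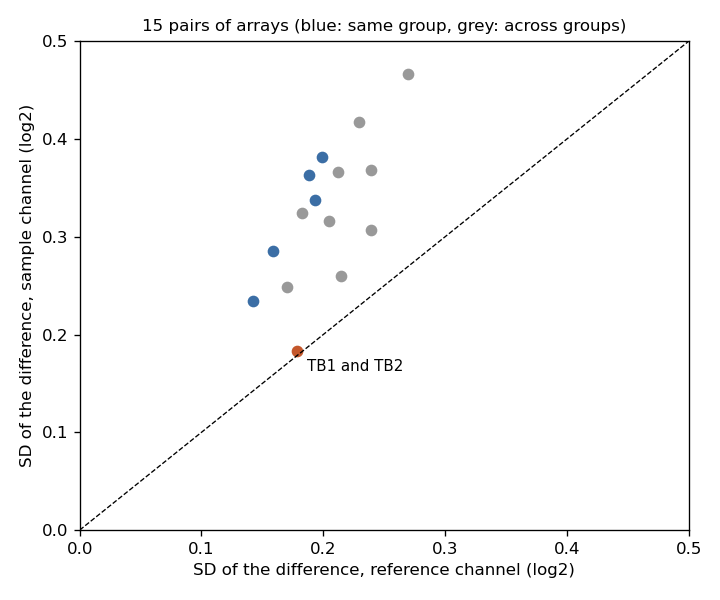
SD of the log2 difference in the sample channel (y axis) against that in the reference channel (x axis) for 15 pairs of arrays, with pairs within a group in blue, pairs across groups in grey and a dashed line of equal SD. The pair TB1 and TB2 lay at 0.18 on both axes, and the 14 other pairs lay above the line.

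Differences also followed the GC content of the probe. At up to 35% GC 23.1% of genes were lower at an unadjusted p under 0.05, and above 55% GC 2.18%.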

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

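Alternatives named as added here were chosen after the data were seen; the rest were fixed before the data were examined. The cause was not tested for any change below, except that fewer samples were fitted where arrays were left out. No named gene or list reversed a call under any alternative run. Against 0 higher, 5 lower and 11 lists, with TB_TNF_KO arrays 1 and 2 averaged as chosen after the data were seen, the sample channel alone gave 257, 313 and 3 (follicular dendritic cell, fibroblast, and macrophage lists), with Tnf at -1.17 and past the threshold. Array weights gave 101 and 315, with Tnf at -1.11 and past it. Lower genes and lists were 1 and 3 with the processed signals and loess, and 1 and 3 with the LogRatio. With the authors' processed values they were 0 and 4. The LogRatio and the authors' values gave nearly the same differences (Tnf -1.2754 and -1.2757), so they are not separate alternatives. Male pools by the labels gave 2 and 6, the same fit as leaving out TB_TNF_KO replicate 2. It kept TB_TNF_KO array 1, which lacked Y-linked signal, so it does not test sex. Without background subtraction 0 genes were lower, and 2 with the mean of all probes, with Tnf at -0.58 and -0.68. Over all alternatives Tnf lay between -1.28 and -0.58. Median centring gave 6 lower genes and 15 lists. The intensity trend gave 3 lists, camera with an estimated correlation 0 and fry 0. Loess with Aquantile leaves log ratios as they were and so tests nothing. The extraction day could not be run as a block, since each day held 1 group.

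Leaving out each replicate gave 0 to 0 higher genes, 0 to 4 lower genes, 4 to 13 lists and a Tnf difference of -1.17 to -0.99. Leaving out TB_TNF_KO replicate 3 left a lone sample, assumed to vary like the other group.

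The 6 arrays separately, the design fixed before the data were examined, gave 541 higher and 1734 lower and 8 lists, with Tnf at -1.06 past the threshold. With the replicate block added, 684 genes were higher and 2399 lower, with Tnf at -1.06 and past the threshold. Deviations from group means correlated at 0.14, 0.52 and 0.62 for equal numbers. As TB_TNF_KO arrays 1 and 2 count as 1 sample, fewer than 3 pairs remain and the numbers were not taken to pair the samples, although replicate 3 of both groups lacked pancreas transcripts (0.03 and 0.02). Not every array correlated best with its own number (TB_TNF_KO array 1 with B_TNF_KO array 2, 0.41).

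Added alternatives were as follows. The GC correction with the 6 arrays separately gave 651 and 1221 (Tnf -1.06), and with the replicate block 731 and 1459 (Tnf -1.06). The pancreas signal as a block, replicate 3 of both groups against the rest, gave 1 higher and 4 lower. Leaving out the arrays without Y-linked signal gave 0 lower, but left TB_TNF_KO replicate 3 as a lone sample, assumed to vary like the other group, and says nothing of sex. An adjusted p under 0.1 gave 323 higher and 1046 lower. On at least 3 arrays 40031 probes exceeded the 95th percentile of negative controls, and with these 0 genes were higher and 4 lower. So lax a cutoff does not tell expressed transcripts from nonspecific signal.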

Other observations

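The tests of the technical explanations below were chosen after the results were seen, and the tests of islet hormone genes and of genes beside Tnf were set before their results were seen.

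In the T helper and regulatory T cell list, 1 of 21 measured members was higher and 3 lower adjusted over the list alone, and 0 over all genes. Ikzf2, a transcription factor of regulatory T cells, differed by 0.28 (SE 0.04), the costimulatory receptor gene Icos by -0.39 (SE 0.07) and Tbx21, the T helper 1 transcription factor gene, by -0.39 (SE 0.09). In the plasma cell list 7 of 12 measured members had higher and 5 lower values (median 0.02, camera adjusted p = 0.95). Adjusted over the list alone 2 were lower, Tnfrsf17, the BCMA gene, at -0.29 (SE 0.05) and Sec11c at -0.32 (SE 0.06), and 0 higher. Cell cycle genes had a list median of -0.0022 and 0 of 23 members passed adjusted over the list alone.

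TB_TNF_KO arrays 1 and 2 agreed closely. Only 4 probes differed over 2-fold, fewer than between any other pair, which restates the agreement, so one RNA on both arrays stays open. Male and female pools as labelled were argued against by a difference of 0.025 in Eif2s3y between these arrays. A pair of like female pools with 1 wrong label stays open too, since the ratio of sample to reference spread by MAD, 1.08, comes from 1 pair. No biological explanation was tested.

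Exocrine pancreas transcripts were present on 4 arrays, and 18 of 18 measured members were higher on each of these than on both others, which is no test of their source, since this list picked the arrays. Pancreas tissue in some pools stays open, since 1 of 6 islet hormone genes was higher on these arrays (median difference 0.03), which did not exclude tissue with few islets. Genotype as the cause was argued against by a range of 4.02 in the list median within B_TNF_KO. Among the 10 splits of the 5 samples into 3 and 2, 2 gave at least 5 called genes, the real one (5) and 1 other (12). That other split set replicate 3 of both groups, those without pancreas transcripts, against the rest, which points to a structure of the samples; the splits are too few for a share under 0.05.

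The 5 genes lower in TB_TNF_KO might rest on the arrays and not the genotype. A smooth trend with probe GC content as the whole cause was argued against, since all 5 passed after the GC correction (Cxcl13 -1.54, SE 0.09). That trend was small, with a median difference of -0.06 at up to 35% GC and 0.03 above 55%. The correction does not reach an effect particular to 1 probe. Lyve1 was set apart from the other 4 genes after its value was seen. In the sample channel alone Cxcl13 (-1.94, limma adjusted p = 0.012), AK017936 (-0.99, 0.047), AK031739 (-0.63, 0.047) and Prg4 (-0.39, 0.047) passed. Lyve1 (-0.42, 0.067) did not. Apart from Cxcl13 these lay close to the threshold, so passing or failing there decides little. For Cxcl13 (-0.75) and AK017936 (-0.17) the reference channel was lower in TB_TNF_KO, which raises the ratio. The reference channel as the whole cause was thus argued against for these genes. For Lyve1, Prg4 and AK031739 the reference differed by 0.54, 0.26 and 0.23, so part of their difference may come from the reference. The sample channel may itself carry an effect of the day. Extraction day and genotype cannot be told apart, since each day held 1 group. In the reference channel 8526 genes had an unadjusted limma p under 0.05, where chance gives 1852.

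A hypothesis that DNA flanking the targeted Tnf allele would carry more differences than other regions was tested on the 100 measured genes nearest Tnf by order in GRCm38.p6. There 8 had an unadjusted p under 0.05, and 98.3% of runs of 100 neighbouring genes on other chromosomes held as many or more, with a median of 21. By the labels Tnf was targeted in both groups, so both may carry the same flanking DNA and this comparison could not show it. The bound set before the result overlooked this, and the hypothesis stays open.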
